A study of Mus musculus with 7 samples.

How the data were processed

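Gastric glands were isolated from the corpus and the pylorus of C57BL/6 mice, digested to single cells and sorted as living, DAPI-negative cells into 384-well plates for CEL-seq2, per the labels' protocols. The deposited tables hold raw UMI counts per gene and well, per the file headers and the values, which are whole numbers up to 4095, the ceiling of a 6-base UMI. Reads were aligned to mm9, per the submitters' processing notes. The aligner and the counting tool are not given in the sources used here. Genes are named with their chromosome in the tables, and these names were used as given, without coordinates, since the reference at hand is of another build. The tables hold 18907 features besides 81 spike-in RNAs. Genes that share reads with near-identical copies may be split by the authors' counting, and the tables do not say how.

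Each plate was taken as 1 replicate of the region in its label, 4 for corpus and 3 for pylorus. Wells with at least 1000 UMIs, spike-ins left out, were kept as cells, without a limit on mitochondrial transcripts. No doublet caller was run, since a sorter filled each well. The plates held 2646492 to 9511078 UMIs, and spike-ins took 4.27% and 6.55% of the UMIs of corpus replicate 1 and pylorus replicate 1 against 0.256% to 0.426% of the other 5 plates. Intervals and floors, a floor being 3 counts, cover counting error only.

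Cells were scaled to 10000 UMIs, log-transformed and clustered in scanpy 1.11.5 (2000 variable genes less mitochondrial ones, 30 principal components, 15 neighbours, Leiden resolution 1.0 in igraph 0.11.9), over all plates without batch correction. A cluster took the name of the class whose detected markers, seen in more than 25% of its cells, had the largest mean log2 fold over the other cells, if at least 3 markers were detected and the mean was at least 0.5. It stayed unnamed where its 10 leading genes held more markers of another class, or where it was shallow and none of its own markers led. The markers were fixed before the data were examined. The naming rule was not: 3 rules were tried in order, each replaced after seeing which clusters it named and how the classes fell over the plates, and before any comparison of the regions. The first counted markers at 2-fold or more and took the class with the largest share of its markers. The second counted markers above 1-fold and took the largest mean over all markers, and it gave the same classes as the third. Under the first, 19 cells were neck-like, all of them in corpus replicate 1, and neck-like and proliferating-like cells could not be compared.

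Counts were summed per plate over all kept cells, and per class where a plate held at least 10 of its cells. The design fixed before the data were examined was a quasi-likelihood model for counts. The layout of the tables did not pass the unit check that count models require here, so limma was used in their place on log2 CPM. Sums were scaled by trimmed means of M values (TMM, trimming 30% of log ratios and 5% of abundances), genes with low counts were left out (a minimum of 10 counts at the median library size in as many plates as the smaller group, and 15 in total), and log2 CPM with a pseudocount of 2 was fitted in limma 3.58.1 (R 4.3.3) with a mean trend. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The CPM printed for these fits are TMM-scaled, and those of Gast and of genes in single classes of cells outside the fits are scaled to all UMIs of those cells. Gene lists were tested by camera with a preset correlation of 0.01 and again with an estimated one. In all, 24 lists were fixed before the data were examined, and the stromal, squamous forestomach, pancreatic acinar, red blood cell and sex-linked lists had too few tested genes in the sums over all cells. Shares of cells were compared by exact permutation tests in scipy 1.17.1, two-sided over 35 splits of the plates.

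Genes were named by a rule fixed before the data were examined: among genes that passed, with at least 32 CPM on average in one region and no overlap between the plates of the regions, the 10 (all cells) or 6 (a class) with the largest change in each direction, up to 4 members of each list that passed or else its 2 most abundant, and 18 gastric marker genes always. The same rule was applied to the 4 similar plates.

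The fits were tested on simulated counts with 200 genes changed. Every gene was given 1 spread, the median of the real plates, and no grouping of plates was simulated. Genes that vary more between plates would be recovered less often. In this setting, called the real spread here, the sums over all cells recovered 38% of genes changed 2-fold and 96% of those changed 4-fold, with 6 false calls among 140. At a lower simulated spread it recovered 91% of 2-fold changes, so the spread between plates limited the precision there. The same simulation at the real spread recovered 38% of 2-fold and 90% of 4-fold changes for neck-like, 37% and 90% for pit-like, 31% and 90% for chief-like, 43% and 85% for parietal-like, 11% and 75% for proliferating-like and 5% and 65% for endocrine-like cells, and 7% and 54% for the comparison between classes. For parietal-like cells the real spread was at its set minimum of 0.01, the same as the lower one. A 2-fold change would mostly have been missed in the classes where no gene passed.

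Alternatives tried were median-of-ratios scaling, no filter on low counts, other UMI minimums (500 and 2000), all wells, mitochondrial limits, a correction for UMI collisions, thinning of each cell to 1000 UMIs, other clustering resolutions (0.5 and 2.0), other hormone minimums, the replicate number as a block and each plate left out. Chosen after seeing the data were a pseudocount of 0.5, voom weights, Rn45s left out, the earlier naming rules, the shallow plates left out, the plate set as a term, the 4 similar plates alone, also with an estimated correlation, and each plate's level of hormone transcripts in other cells subtracted.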

Results

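Single cells of gastric epithelium from C57BL/6 mice were profiled by SORT-seq. In this plate-based method a sorter puts 1 living cell into each well. The CEL-seq2 chemistry then counts its transcripts by unique molecular identifiers (UMIs). The data comprised 4 plates labelled corpus, the acid-producing main body of the stomach, and 3 plates labelled pylorus, its outlet, each with 384 wells. Of 2688 wells, 2235 held at least 1000 UMIs and were kept as cells, 1252 from corpus and 983 from pylorus plates. Corpus replicates 1 to 4 held 2733107, 5952905, 9511078 and 8856753 UMIs in all wells. Pylorus replicates 1 to 3 held 2646492, 8261045 and 9046406. The median kept cell held 6899, 19648, 25381 and 25545 UMIs in corpus replicates 1 to 4, and 8240, 20326 and 23400 in pylorus replicates 1 to 3. The labels do not say which plates came from which animals, so the p-values of shares measure the spread between plates. Those of single genes rest on the gene's own spread between plates and on that of other genes, pooled by limma. Where only 2 plates per region were fitted, the pooled part outweighed the gene's own. P-values of gene lists with the preset correlation of 0.01 set genes against other genes, taken as nearly independent. They do not measure the spread between plates. The labels name the region as the only difference between the groups, and the comparisons asked how the cell make-up and the transcripts of the regions differed.

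Plates of both regions held the main cell classes of gastric glands. Mucous neck or gland-like cells, named by Muc6, Tff2 and A4gnt, made up 26.9% ± 1.4 (SD, n = 4) of the kept cells in corpus plates and 25.1% ± 1.6 (SD, n = 3) in pylorus plates. Surface mucous (pit)-like cells, marked by the mucin Muc5ac and the peptides Gkn1, Gkn2 and Tff1, made up 18.6% ± 11.5 and 22.1% ± 3.1. Chief-like cells, which make digestive pre-enzymes such as Pgc, made up 12.0% ± 10.1 and 17.5% ± 1.1. Parietal-like cells, which carry the acid pump of Atp4a and Atp4b, made up 8.01% ± 7.11 and 3.31% ± 2.11. Endocrine-like cells made up 14.5% ± 10.7 and 10.5% ± 2.8, and proliferating-like cells 8.03% ± 8.29 and 7.73% ± 1.81. Immune-like cells made up 4.19% ± 4.09 and 7.12% ± 4.58, and tuft-like cells 2.00% ± 0.89 and 2.35% ± 1.03. No class differed between the regions by more than the spread between plates (exact two-sided permutation test over 35 splits, unadjusted p at least 0.171, smallest possible p 0.0286, adjusted p at least 0.964 in 9 classes). Adjusted over 9 classes, a single class at that smallest p could not pass, so the adjusted test had little power. Among corpus plates, parietal-like cells were 15.5% and 12.6% of replicates 3 and 4 but 1.08% and 2.87% of replicates 1 and 2. Clusters without a name held 15.8%, 7.17%, 0% and 0.299% of corpus replicates 1 to 4 and 12.8%, 0% and 0% of pylorus replicates 1 to 3. A count of 0 allows up to 1.05%, 1.04% and 1.03% in the plates at 0 (95% Wilson intervals). Different clusters held the same class in different plates. Corpus replicates 1 and 2 and pylorus replicate 1 supplied nearly all cells of one neck-like, one pit-like and one chief-like cluster, and the other 4 plates nearly all cells of another of each class. A 19-cell neck-like cluster led by Gkn3, Cela1 and Aqp5 came from the library labelled corpus replicate 1 alone.

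**Figure D1:**
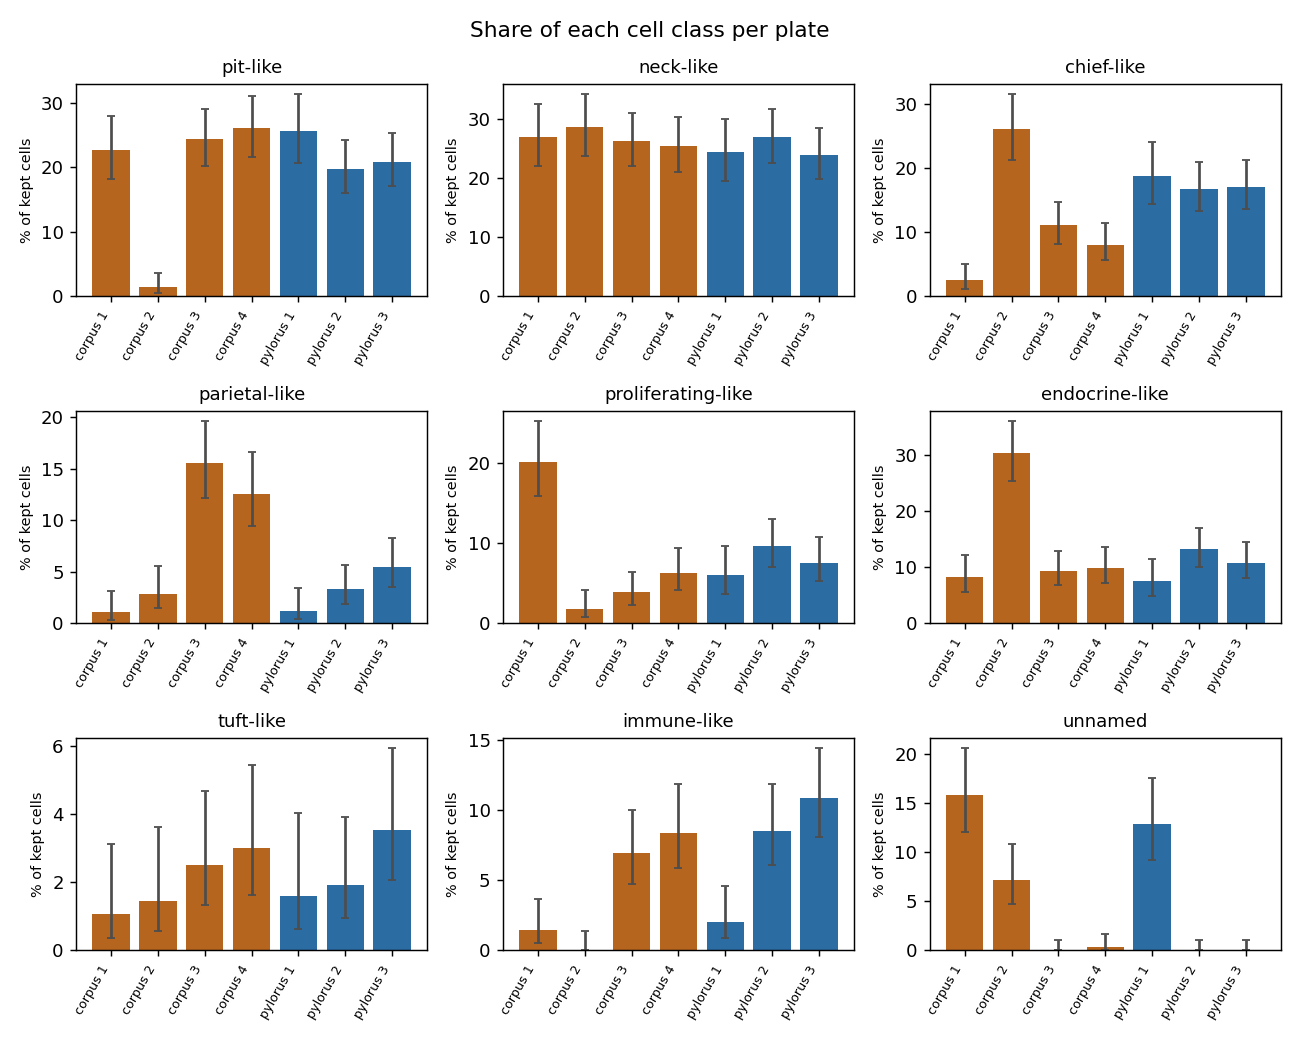
Share of kept cells (percent, vertical axis) in each of 9 classes for each plate (horizontal axis), with corpus plates in brown, pylorus plates in blue and bars for 95% Wilson intervals of counting error. Neck-like cells took 26.9% of corpus and 25.1% of pylorus plates on average, while the other classes varied widely between corpus plates.

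Endocrine-like cells were sorted by the hormone transcript they held most of. Ghrl, which encodes the appetite hormone ghrelin, led in 38.5% ± 18.6 (SD, n = 4) of endocrine-like cells of corpus plates and 57.7% ± 23.0 (SD, n = 3) of pylorus plates. Hdc, the enzyme of histamine synthesis, led in 38.4% ± 14.2 and 32.5% ± 12.9. Sst, which encodes somatostatin, led in 13.3% ± 12.6 and 4.90% ± 5.30. Gast, which encodes gastrin, led in 5 of 23 endocrine-like cells of the library labelled corpus replicate 1 (21.7%, 95% Wilson interval 9.66 to 41.9%) and in 0 of 19, 48 and 40 in pylorus replicates 1 to 3, where the same interval reaches 16.8%, 7.41% and 8.76%. Across all kept cells, Gast had 3340 UMIs in that library and 0 in each of the other 6, where 3 counts correspond to 0.316 to 1.15 CPM (counts scaled to a fixed total per plate). Tph1, an enzyme of serotonin synthesis, led in no cell. No hormone share differed between the regions (exact two-sided permutation test, unadjusted p at least 0.286, smallest possible p 0.0286, adjusted p = 1 for each). Here too, a single share at that smallest p could not pass after adjustment. Ghrl, Sst and Atp4b transcripts were also found in classes that should lack them. In immune-like cells, Ghrl stood at 391 and 105 CPM in corpus replicates 3 and 4 and 1168 and 1332 CPM in pylorus replicates 2 and 3. The Ghrl level of the cells outside the endocrine-like class alone would let Ghrl lead in 68.2% of endocrine-like cells of corpus replicate 2 and in 87.5% and 97.5% of pylorus replicates 2 and 3 if these held no hormone transcripts of their own. On the same terms Ghrl would lead in 14.7% of those of corpus replicate 3, and in 0% of those of corpus replicates 1 and 4 and pylorus replicate 1. With that background subtracted in each plate, a step chosen after seeing the data, Ghrl led in 38.2% ± 18.3 of endocrine-like cells of corpus and 55.4% ± 20.8 of pylorus plates.

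Across all kept cells of a plate, Bpifb1 and Lrp2 were the genes that differed between the regions. Bpifb1, a secreted protein of mucosal surfaces, stood at 20.5 ± 6.83 CPM in corpus plates (SD, n = 4) and 233 ± 109 CPM in pylorus plates (SD, n = 3), a log2 difference of 3.45 ± 0.35 (SE, adjusted p = 0.0432, limma), and was higher in every pylorus plate than in any corpus plate. Lrp2, an endocytic receptor, stood at 0.0785 ± 0.157 and 12.1 ± 4.35 CPM, with a fitted log2 difference of 5.01 ± 0.51 that depends on the pseudocount (adjusted p = 0.0432, limma). Lrp2 lay under the abundance minimum for named genes and was named after its values were seen. Of 12003 genes tested, 2 passed and 153 had an unadjusted p under 0.05. Both calls ended when any 1 plate was left out, with a smaller pseudocount and with voom weights. The log2 difference of Bpifb1 stayed between 3.09 and 3.72.

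None of the gastric marker genes passed over all cells, and several varied widely between plates of one region. Pgc stood at 73820 ± 28830 CPM in corpus and 94270 ± 12740 CPM in pylorus plates, and Tff1 at 22140 ± 12320 and 28920 ± 3911. Gkn1 stood at 9317 ± 5690 and 16250 ± 1465, Gkn2 at 17160 ± 9056 and 28720 ± 5831, and Tff2 at 8238 ± 7005 and 6921 ± 752. Muc6 stood at 195.8 ± 54.5 and 83.5 ± 63.6 CPM with a log2 difference of -1.44 ± 0.43, and Atp4a at 664 ± 369 and 293.5 ± 147 CPM (-1.14 ± 0.49). Atp4b (1384 ± 1556 and 601 ± 488 CPM), Muc5ac (903.5 ± 575 and 955 ± 960), Chga (5518 ± 6698 and 3492 ± 1709), Ghrl (1514 ± 1576 and 2723 ± 1233), Sst (1060 ± 512 and 614 ± 899), Gif (1937 ± 1791 and 1955 ± 1461), the stem cell markers Lgr5 (13.5 ± 4.43 and 7.19 ± 2.34) and Aqp5 (35.2 ± 44.97 and 8.12 ± 2.50) and the proliferation marker Mki67 (112 ± 108 and 87.0 ± 24.1) did not pass either (limma, adjusted p = 0.9998 for each of these genes). Pdx1, a transcription factor of the distal stomach and duodenum, had too few counts to be tested.

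**Figure D2:**
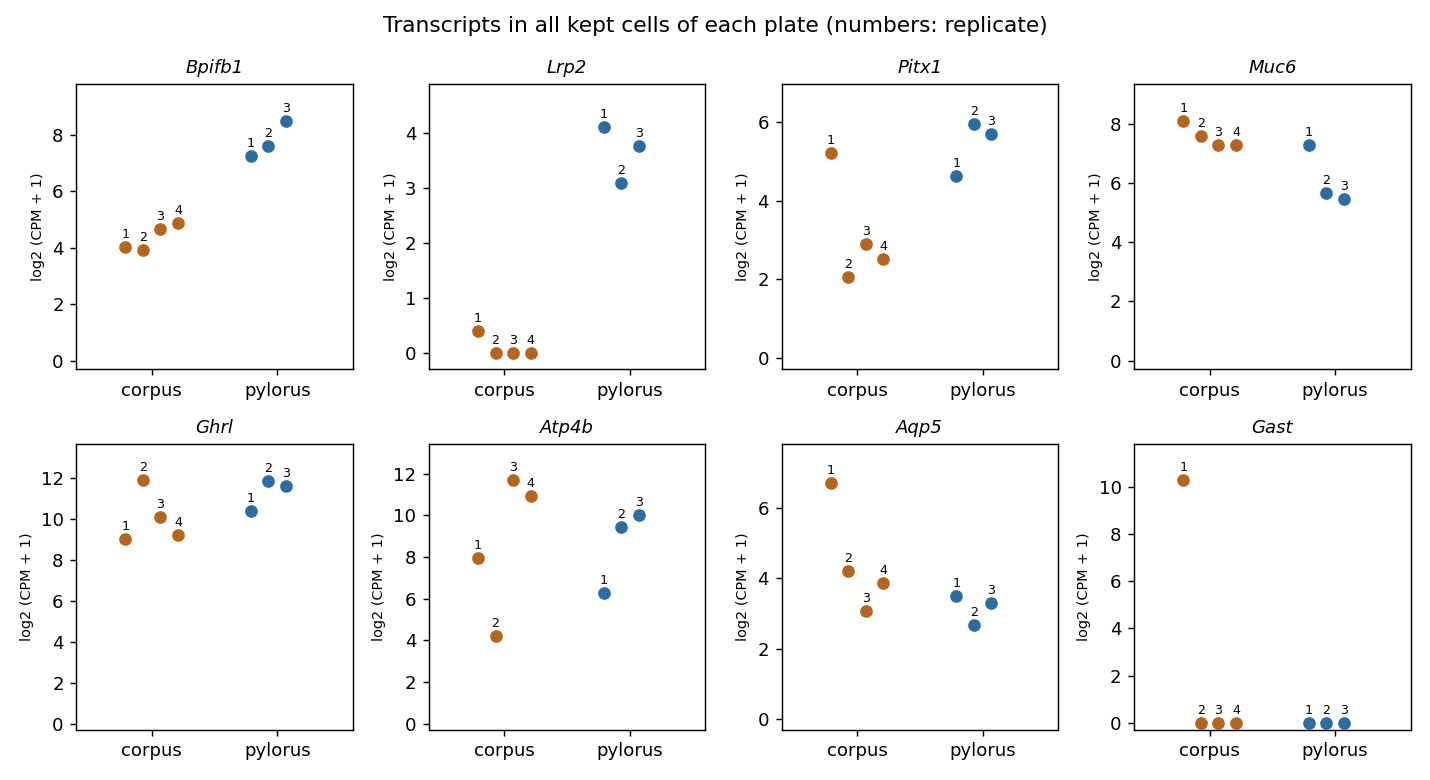
Transcripts of 8 genes in all kept cells of each plate, as log2 of CPM plus 1 (vertical axis), for the corpus (brown) and pylorus (blue) plates, each point being 1 plate labelled by its replicate number. Bpifb1 and Lrp2 were higher in the 3 pylorus plates than in the 4 corpus plates, and Gast was found in the library labelled corpus replicate 1 alone.

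Of the 19 gene lists that could be tested over all cells, 8 passed with a preset correlation (camera in limma), 6 of them higher and 2 lower in pylorus plates, and none with an estimated correlation (lowest adjusted p = 0.221 with an estimated correlation). The pit list was higher (7 of 8 members, median log2 difference 0.56, adjusted p = 0.00179, 0.326 with an estimated correlation), as were the immune list (7 of 7 members, 1.38, adjusted p = 0.000156, 0.326 with an estimated correlation), the tuft list (7 of 8, 0.81, adjusted p = 0.0303, 0.632 with an estimated correlation) and the antimicrobial and barrier list, with Pigr and Wfdc2 (4 of 4, 0.61, adjusted p = 0.0051, 0.221 with an estimated correlation). Both Pigr and Wfdc2 overlapped between plates of the regions. Scaled to all UMIs, corpus replicate 1 held 116 CPM of Pigr and 108 CPM of Wfdc2, and pylorus replicate 1 held 11.9 and 77.6 CPM. The regional transcription factor list was higher by a median of 0.20 (8 of 12 members, adjusted p = 0.048), with Irx5 at 7.68 ± 5.32 and 36.5 ± 16.4 CPM. Its other 4 members were lower. Nkx6-3, a homeobox gene of the distal stomach, was lower by -4.39 ± 0.43 (log2, SE) in corpus replicates 3 and 4 and pylorus replicates 2 and 3 alone. It lay under the floor of 3 counts in these pylorus plates, so the size of its difference depends on the pseudocount. Pdx1, also of this list, was not tested. The neck list, with Muc6 and A4gnt, was lower (2 of 4 members lower, median -0.44, adjusted p = 0.00364), as was the gland base stem list (6 of 9 lower, -0.56, adjusted p = 0.00689). These 3 lists had an adjusted p of 0.221 with an estimated correlation. Within corpus replicates 3 and 4 and pylorus replicates 2 and 3 alone, the pit list turned to a median of -0.15 and the tuft list to -0.13, and with cells thinned to 1000 UMIs the regional transcription factor list turned to -0.0236. In the same 4 plates the immune list was at 0.29 (4 of 7 members higher, adjusted p = 0.242) and the gland base stem list at -0.31 (adjusted p = 0.0906), so neither passed. With thinned cells the tuft list (adjusted p = 0.17) and the dissociation stress list (adjusted p = 0.0509) did not pass. The parietal list (median -0.64, adjusted p = 0.00372 in camera) and the mitochondrially encoded list (-0.27, adjusted p = 0.0126) came to pass there, both lower. Genes of dissociation stress, a sign of sample handling, were higher too (11 of 12, 0.25, adjusted p = 0.000156, 0.221 with an estimated correlation). No member of any list passed over all genes. Adjusted over the list alone, 2 neck list members were lower and 1 member each of the pit, regional transcription factor and dissociation stress lists was higher. The chief, parietal, proliferating, endocrine, endothelial, intestinal, antigen presentation, mucin glycosylation, ER secretory machinery, nuclear oxidative phosphorylation and mitochondrially encoded lists did not pass (lowest adjusted p = 0.0521 in camera), and the endocrine list had a median of 0.02 and a mean of -0.06 on the log2 scale. Without pylorus replicate 1, 5 lists passed.

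In mucous neck or gland-like cells, Bpifb1 and Lrp2 were higher and Amotl1 was lower in pylorus plates. Bpifb1 rose from 31.3 ± 18.3 CPM (SD, n = 4 plates) to 732 ± 380 CPM (SD, n = 3), a log2 difference of 4.54 ± 0.42 (SE, adjusted p = 0.00439, limma). Lrp2 rose from 0.447 ± 0.895 to 48.7 ± 20.8 CPM (4.77 ± 0.49, adjusted p = 0.00568, limma). Amotl1, a regulator of cell junctions and of the Hippo pathway, fell from 70.2 ± 25.2 to 9.96 ± 4.87 CPM (-2.68 ± 0.33, adjusted p = 0.0221, limma). All 3 genes separated the 4 corpus plates from the 3 pylorus plates without overlap, and they were the only genes to pass of 9363 tested, with 292 at an unadjusted p under 0.05. The class name rests on 3 detected markers, and of these Muc6 stood at 825.6 ± 324 and 358 ± 290 CPM (-1.42 ± 0.44, adjusted p = 0.999, limma). The Bpifb1 call held without any 1 plate, while that of Lrp2 ended without pylorus replicate 1 or 3 and with a pseudocount of 0.5. That of Amotl1 ended without corpus replicate 2, 3 or 4 and without pylorus replicate 2 or 3. Bpifb1 was also a leading gene of the cluster that held most neck-like cells of corpus replicates 3 and 4 and pylorus replicates 2 and 3.

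No gene passed in pit-like, chief-like, proliferating-like or endocrine-like cells over all plates (limma, 206, 186, 140 and 117 genes at an unadjusted p under 0.05, and 1, 0, 0 and 0 genes with voom weights). In pit-like cells, Sgk1, a kinase of ion transport, had 38.4 ± 18.1 CPM in corpus and 307 ± 61.9 CPM in pylorus plates (SD, n = 3 each, log2 difference 3.06 ± 0.34, adjusted p = 0.109, limma), and the homeobox gene Meis2 had 29.6 ± 5.19 and 6.07 ± 1.04 CPM (-2.11 ± 0.27, adjusted p = 0.13, limma). In chief-like cells, the homeobox gene Pitx1 had 1.005 ± 0.144 and 26.4 ± 11.2 CPM (SD, n = 3 each, adjusted p = 0.132, limma), and Bpifb1 had 20.2 ± 15.3 and 152 ± 14.97 CPM (3.09 ± 0.45, adjusted p = 0.132, limma). In proliferating-like cells, Bpifb1 had 5.26 ± 5.02 and 133.5 ± 95.2 CPM (4.08 ± 0.58, adjusted p = 0.325, limma), and in endocrine-like cells the imprinted gene Nnat had 234 ± 229 and 14.4 ± 4.47 CPM (-3.26 ± 0.59, adjusted p = 0.986, limma). Sgk1, Meis2, Pitx1 and Nnat were named after their values were seen, as the genes with the smallest p of these fits. Leaving out 1 plate gave at most 2 genes in pit-like, 3 in chief-like, 5 in proliferating-like and 0 in endocrine-like cells, the largest counts coming without corpus replicate 1 for pit-like and without pylorus replicate 1 for chief-like and proliferating-like cells. Tuft-like cells reached 10 cells in only 1 plate per region and were not tested. Of the gene lists, 9 of 17 passed in pit-like, 8 of 16 in neck-like, 1 of 15 in chief-like, 2 of 15 in proliferating-like and 0 of 12 in endocrine-like cells with the preset correlation of camera, and none with an estimated one. Dissociation stress genes were among them, with 12 of 12 higher in pit-like (adjusted p = 1.41e-05, 0.359 with an estimated correlation) and neck-like cells (adjusted p = 0.000836, 0.159) and 9 of 11 in proliferating-like cells (adjusted p = 0.00362, 0.274).

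Parietal-like cells reached 10 cells only in corpus replicates 3 and 4 (56 and 42 cells) and pylorus replicates 2 and 3 (12 and 20 cells). In these plates 476 of 6860 genes differed, 216 higher and 260 lower in pylorus plates (limma). The p-values of this fit rest mostly on other genes. A gene's own spread had 2 degrees of freedom, and the spread pooled over genes 13.9. The 4 plates can be paired in only 3 ways, so the real pairing comes first by chance 1 time in 3. Meg3, an imprinted noncoding RNA, fell from 307 ± 117 to 6.88 ± 4.98 CPM (SD, n = 2 each, log2 difference -5.24 ± 0.35, adjusted p = 5.56e-07, limma), and the glycosyltransferase B4galnt2 fell from 80.5 ± 4.15 to 0.56 ± 0.792 CPM. Prlr, Ifi27l2a and Zcchc11 were also lower. Tfrc, the transferrin receptor, rose from 66.8 ± 4.64 to 277 ± 31.2 CPM (2.02 ± 0.17, adjusted p = 8.69e-06, limma), the sterol pathway enzyme Idi1 from 20.2 ± 8.69 to 90.2 ± 7.02 CPM, and Car9, a carbonic anhydrase induced by low oxygen, from 24.5 ± 1.92 to 86.8 ± 2.27 CPM. The photoreceptor gene Rom1 and Bpifb1 were higher too. The pump genes Atp4a (4447 ± 46.4 and 4064 ± 157 CPM) and Atp4b (11190 ± 406 and 9183 ± 801 CPM) did not pass (adjusted p = 0.67 and 0.347, limma). All 9 mitochondrially encoded genes of the list were lower (median log2 difference -0.66, adjusted p = 3.23e-05 in camera, 0.466 with an estimated correlation), and 11 of 12 nuclear genes of oxidative phosphorylation were higher (0.32, adjusted p = 0.000543, 0.466 with an estimated correlation). Of 11 dissociation stress genes 10 were higher as well (0.56, adjusted p = 0.00806, 0.503 with an estimated correlation). The intestinal, gland base stem, neck and chief lists were lower (adjusted p = 0.00176, 0.00232, 0.018 and 0.0202 in camera, at least 0.466 with an estimated correlation). Whether neck and chief list transcripts in these cells were free RNA of other cells was not tested. Ghrl rose (1.80 ± 0.21, adjusted p = 0.00016, limma) and Sst fell (-4.71 ± 0.86, adjusted p = 0.00379, limma) in these cells as they did in the other classes of the same plates. The count was 153 and 142 without corpus replicates 3 and 4, 1137 and 1389 without pylorus replicates 2 and 3, where a lone plate is assumed to vary like the other region's, and 37 of 309 genes tested, 7 higher and 30 lower, with each cell thinned to 1000 UMIs. With voom weights it was 663, of which 385 were higher and 278 lower.

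The region difference itself was compared between neck-like and pit-like cells of the 6 plates that held both, with the plate as a block. No gene had a region difference that differed between these classes (limma, 9609 genes tested, 335 at an unadjusted p under 0.05, smallest adjusted p = 0.0702, 1 gene with voom weights), so Bpifb1, Lrp2 and Amotl1 were not shown to differ in neck-like cells alone.

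The plates also fell into groups that the labels do not give. Over all genes, profiles of corpus replicates 3 and 4 and pylorus replicates 2 and 3 correlated at 0.966 to 0.984 (Pearson, log2 CPM, across genes, which are not independent replicates), and corpus replicate 1 correlated most with pylorus replicate 1 (0.925). By correlation the other 3 plates were not a set, since pylorus replicate 1 correlated most with pylorus replicate 2 (0.927), and corpus replicates 1 and 2 least of all pairs (0.817), although these 3 plates shared clusters. Within the 4 similar plates, compared after seeing this, 429 of 11978 genes differed between the regions over all cells, 201 higher and 228 lower in pylorus plates (limma). Picking plates from the same data for similar profiles favours a small spread between plates of one region, on which these p-values rest. The adjusted p-values and counts of genes from this choice, over all cells and by class, are therefore not valid error rates. The other 3 plates hold 1 pylorus plate, too few for such a test, and pylorus replicate 1 minus corpus replicate 1 had the same sign for 261 of these 429 genes (60.8%). The same sign was found for 97 of the 147 genes called in neck-like, 107 of 204 in pit-like, 15 of 20 in endocrine-like and 9 of 20 in proliferating-like cells of the similar plates. With the plate set as a term over all 7 plates, 2 genes passed.

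In the 4 similar plates, the pylorus plates had higher Bpifb1 (log2 difference 3.32 ± 0.21, adjusted p = 3e-06, limma), the homeobox genes Pitx1 (3.29 ± 0.18) and Irx5 (2.06 ± 0.18), the alarmin Il33 (3.19 ± 0.20), the lipoprotein gene Apob (2.76 ± 0.19), the activin antagonist Fst (3.45 ± 0.36), the milk-clotting enzyme Cym (5.43 ± 0.85) and the interferon-induced Ifit1 (2.05 ± 0.16) and Isg15 (2.04 ± 0.19). They had lower Muc6 (-1.74 ± 0.12, adjusted p = 3e-06, limma), A4gnt (-1.04 ± 0.11), Nkx6-3 (-4.39 ± 0.43), Aqp4 (-3.04 ± 0.22), the fatty acid carrier Cd36 (-2.89 ± 0.28), Atp4a (-1.37 ± 0.22) and Atp4b (-1.58 ± 0.23). The sizes for Cym and Nkx6-3 depend on the pseudocount. Cym stood at 0 CPM in corpus replicate 3, and Nkx6-3 lay under the floor of 3 counts in both pylorus plates. All 9 members of the parietal list were lower there (adjusted p = 3.89e-12 in camera with the preset correlation), and all 10 of the proliferating list were higher (adjusted p = 3.67e-07), at 0.282 and 0.353 with an estimated correlation. In these plates parietal-like cells were 14.0% of corpus and 4.36% of pylorus cells, and proliferating-like cells 5.08% and 8.60%. By class, 204 genes differed in pit-like, 147 in neck-like, 39 in chief-like, 20 in proliferating-like and 20 in endocrine-like cells of these plates, and 48 genes had a region difference that differed between neck-like and pit-like cells. In these plates 39 genes passed in at least 3 classes, and since the classes share plates and free RNA of a plate was not excluded, their common direction is not independent evidence. Among them were Bpifb1 and Dpcr1, higher in 5 classes each, and Pitx1 and Irx5, higher in 4 each. Ghrl was higher, and Sst and Muc5ac lower, in all 6 classes, and Atp4a and Atp4b were lower in 4. Over all 7 plates, Pitx1 (2.39 ± 0.76), Il33 (3.12 ± 0.65), Apob (2.10 ± 0.71), Fst (2.30 ± 1.83), Ifit1 (1.72 ± 1.85) and Isg15 (1.87 ± 1.63) did not pass (adjusted p = 0.9998 for each, limma), nor did Cym (6.79 ± 1.04, adjusted p = 0.451, limma). Fst stood at 197 CPM in corpus replicate 2 against 12.6 to 34.1 CPM in pylorus plates, Apob at 5.52 CPM in pylorus replicate 1 against 5.96 CPM in corpus replicate 1, and Ifit1 at no more than 1.57 CPM in corpus replicates 1 and 2 and pylorus replicate 1. Pitx1 stood at 36.1 CPM in the library labelled corpus replicate 1 and 23.6 CPM in pylorus replicate 1.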

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

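The test of Pdx1 below was chosen after the gastrin result was seen. In 37 sets of 4 corpus plates, 11 had 1 plate far from the other 3, and 10 of the 11 plates were corpus replicate 1 or 2. Chance flags about 1 in 20 sets of independent, normally spread values, but the sets here share the same plates. For the Gast share, the share without a hormone gene and Lrp2, the other 3 plates were at 0, where any value above 0 is flagged. The count of 11 is therefore not a fair contrast with that rate.

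Corpus replicate 2 held 1.43% pit-like cells against 22.7% to 26.0% in the other corpus plates, 30.5% endocrine-like cells against 8.27% to 9.88%, and 4615 CPM of Gif, the intrinsic factor gene, against 921 to 1233 CPM. The library labelled corpus replicate 1 held 31000 CPM of Pgc against 84950 to 93820 CPM in the other corpus plates, and 102 CPM of Aqp5 against 7.35 to 17.4 CPM. Spike-in RNAs took 4.27% of its UMIs against 0.256% to 0.426%. Among its endocrine-like cells, Hdc led in 17.4% against 43.5% to 48.5%, Gast led in 21.7% against 0%, and 17.4% reached the minimum of 5 UMIs for no hormone gene against 0%. Its Lrp2 level was 0.314 CPM against 0, which lies under the floor of 3 counts (1.11 CPM) and cannot be told from 0. Sst stood at 299.8 CPM in corpus replicate 3 against 1247 to 1414 CPM in the other corpus plates.

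The library labelled corpus replicate 1 alone held gastrin transcripts, a product of the antral, pyloric part of the stomach in textbooks, and none of the pylorus plates did. A swap of corpus replicate 1 with pylorus replicate 1 would turn round the differences seen in the other plates. Over 147 genes that differed in neck-like cells of the 4 similar plates, pylorus replicate 1 minus corpus replicate 1 had a median of 0.35 (bootstrap SE 0.13) in the direction of those differences. This is above 0 but short of the bound of 3 SE set in advance. In pit-like cells the median was 0.06 (SE 0.06), over the 194 of 204 genes that the filter on low counts kept over all plates. A swap therefore stays open. It would leave pylorus replicates 2 and 3 without gastrin. Cells from gastrin-producing stomach in that plate may be a source, since Pdx1 was highest there among the 7 plates at 2.23 CPM, from 6 UMIs, against 0 to 0.316 CPM. Nkx6-3, whose values are given under the other observations, was also highest in that plate and lowest in the pylorus plates. It was not part of a test set in advance. An outside sample under that label, or a piece of tissue taken across the border of the regions, stays open, and no value in the tables was found to decide between them. Pylorus replicates 1 to 3 held 0 UMIs of Gast and of Pdx1, and they held chief-like and parietal-like cells. These genes thus do not bear out the pylorus label, which was taken as given. The swap test likewise takes the labels of the 4 similar plates as right.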

How the results depend on the processing

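The earlier naming rules, the 4 similar plates (corpus replicates 3 and 4, pylorus replicates 2 and 3), the shallow plates left out, the plate set as a term, a pseudocount of 0.5, voom weights, Rn45s left out, the subtracted hormone background and the estimated correlation in the 4 similar plates were chosen after seeing the data. The planned quasi-likelihood and Wald tests for counts, those on cell numbers included, were not run, for the reason given with the processing, and tuft-like cells gave no value. Depth limits the thinned sums, which leave fewer genes to test, and also the sums of small classes. At the lower simulated spread, 24% of 2-fold changes were recovered in endocrine-like cells against 91% over all cells. The choice of the 4 similar plates favours a small spread between plates, so their larger counts of genes do not carry valid error rates. Unless said otherwise, the cause of a change was not tested.

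Over all cells, 2 genes passed, and 429 in the 4 similar plates, 1 with thinned cells, and 0 with a UMI minimum of 2000, the shallow plates left out, a pseudocount of 0.5 or voom weights. Each plate left out gave 0. In pit-like cells 0 passed, and 204 in the 4 similar plates, which are also those left without the shallow plates and corpus replicate 2, 18 with the plate set as a term, 1 with no filter, voom weights or Leiden resolution 0.5, and 0 to 2 with each plate left out. In neck-like cells 3 passed, and 147 in the 4 similar plates, 15 without the shallow plates, 9 with the plate set as a term, 1 with thinned cells, and 1 to 4 with each plate left out. In chief-like cells 0 passed, and 39 in the 4 similar plates, 8 with the plate set as a term, 3 without a filter or the shallow plates, and 0 to 3 with each plate left out. In parietal-like cells 476 passed, 37 of 309 tested with thinned cells, and 142 to 1389 with each plate left out. In proliferating-like cells 0 passed, and 20 in the 4 similar plates, which are those left without the shallow ones, 3 with the plate set as a term, and 0 to 5 with each plate left out. In endocrine-like cells 0 passed, and 20 in the 4 similar plates, 1 without the shallow plates and 0 with each plate left out. Between neck-like and pit-like cells 0 genes passed, 48 in the 4 similar plates, 1 with voom weights and 0 with each plate left out.

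Of the gene lists, 8 passed, 0 with an estimated correlation, in the 4 similar plates too, and 5 to 11 with each plate left out. The pit list reversed to a median of -0.15 and the tuft list to -0.13 in the 4 similar plates, and the regional transcription factors to -0.0236 with thinned cells. In neck-like cells of the 4 similar plates, Apoa1 reversed to -1.17 and Muc5ac to -0.80.

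Share differences (pylorus minus corpus, percentage points) turned for pit-like cells to -4.89, proliferating-like to 3.52, endocrine-like to 2.36 and tuft-like to -0.0205 in the 4 similar plates, and for proliferating-like to 4.62 without the shallow plates. With each plate left out they ran from -2.28 to 5.92 (pit-like), -2.37 to 3.75 (proliferating-like), -6.05 to 1.35 (endocrine-like), -0.238 to 0.723 (tuft-like), -2.73 to -1.19 (neck-like), 2.43 to 10.3 (chief-like), -7.01 to -2.20 (parietal-like), 1.07 to 5.49 (immune-like), -5.82 to 1.78 (unnamed), 10.6 to 32.3 (Ghrl), -11.9 to -2.70 (Sst) and -13.4 to -2.20 (Hdc). The neck-like difference, -1.80, was -4.97 with Leiden resolution 2.0, -4.78 without cells over 50% mitochondrial, -3.31 and -3.79 with UMI minimums of 500 and 2000, and -0.497 in the 4 similar plates. The chief-like one, 5.58, was 0.68 with a minimum of 500 and 1.81 without the shallow plates. In the 4 similar plates the parietal-like one, -4.70, was -9.69 and that of Hdc, -5.92, was -21.3. No share passed under any alternative. With plates left out or the replicate block none could, since the smallest possible p of the exact tests was 0.0667 to 0.333. The unnamed share turned to 3.96 with Leiden resolution 0.5, 6.67 with a UMI minimum of 500, 1.80 with 2000, 2.20 without cells over 50% mitochondrial, and 0.0901 under the first naming rule. The Gast share difference was 0 in the 4 similar plates and without the shallow plates, and -7.25 to 0 with each plate left out, since 1 plate holds the transcript.

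Plates with one replicate number did not pair throughout: their deviations correlated at 0.44, -0.09 and 0.45 for replicates 1, 2 and 3. Plates with different numbers reached similar values, at 0.46 for corpus replicate 4 with pylorus replicate 3 and 0.35 for corpus replicate 3 with pylorus replicate 2. The replicate 2 plates differed in sex-linked transcripts, with 0 UMIs of Xist in corpus and 2044 in pylorus. With the replicate number as a block over replicates 1 to 3, 1 gene passed over all cells, 3 in pit-like and 1 in chief-like cells, against 0 in each on the same plates without the block, and the block moved no other count of genes, or of lists over all cells, by over 1.5 times.

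Of 6822 values of 378 single genes and lists under alternatives, 6137 stayed on their side of the threshold without counting as moved. Of the others, 194 came to pass it, 116 no longer did, 368 moved and 7 reversed. Among results past the threshold in neither fit, a gene moved if it shifted by more than 1 SE, and a list if its direction turned. Shifts of genes past it in both fits, and of lists that kept their direction, were not counted. Among results past the threshold in neither fit, 496 changed sign, which was not counted as a reversal.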

Other observations

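The tests of a batch, and of other splits of the plates for the fits over all cells and by class, were chosen after the results were seen, as was the share of region differences lost by thinning.

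Corpus replicate 2 held no Xist transcripts and 424 UMIs of Ddx3y, a gene of the Y chromosome, while the other 6 plates held 381 to 2753 UMIs of Xist. The library labelled corpus replicate 1 had 59.97 CPM of Nkx6-3, a homeobox gene of the distal stomach, against 0.47 to 10.02 CPM in the other corpus plates and 0.125 to 0.394 CPM in pylorus plates. Genes of dissociation stress and mitochondrially encoded genes moved within the 4 similar plates too: all 12 stress genes were higher and all 9 mitochondrially encoded genes lower in pylorus plates (camera, adjusted p = 2.02e-08 and 3.67e-07 with the preset correlation, 0.353 and 0.282 with an estimated one).

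Corpus replicates 1 and 2 and pylorus replicate 1 stood apart from the other 4 plates, with 704 genes called by that split over all cells. The split did not rest on the most abundant genes: 732 genes were called without the 20 most abundant, which take 43.1% of the counts. Both fits used trimmed means of M values, which already limit the pull of such genes. The test could therefore hardly have spoken for a few genes taking most of the counts, and it does not decide on that explanation. Lower depth stays open: thinning each cell to 1000 UMIs took the split from 7.27% to 1.19% of the 4637 genes tested in both, as the bound set in advance asks, but it took the region difference of the 4 similar plates from 4.46% to 0.715% as well, so the test cannot tell depth from lost power, and corpus replicate 2 has a median of 19648 UMIs a cell against 20326 in pylorus replicate 2. A library or sequencing batch that the labels do not give cannot be told apart from other differences between these plates, since nothing names a batch. Differences between animals, sex included, were not tested.

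Ghrelin transcripts were higher in pylorus replicates 2 and 3 than in corpus replicates 3 and 4 in every class tested. More ghrelin made in each class is argued against, since immune-like cells shared the difference, at 2.62 on the log2 scale (1.58 to 3.67 between plates), where under 0.5 was asked. Free RNA or leakage between wells of a plate may account for it, since that value lies within 1 of the difference in all cells, 2.20. Endocrine-like cells themselves held 16421 and 8734 CPM of Ghrl in corpus replicates 3 and 4 and 41347 and 30923 CPM in pylorus replicates 2 and 3. Atp4b was lower by 1.67 in immune-like cells and differed by 0.03 in parietal-like cells, both scaled to all UMIs of those cells. With TMM scaling, Atp4b in parietal-like cells was somewhat lower in pylorus plates but did not pass. A difference in Ghrl or Atp4b in a class that does not make it may therefore come from other cells of the plate. Sst stood at 78.1 and 382 CPM in immune-like cells of corpus replicates 3 and 4 and 76.8 and 0 CPM in those of pylorus replicates 2 and 3, so the same may hold for it. Muc5ac was not tested in this way.

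Other splits of the plates were counted for each fit. Over all cells, 2 of 35 splits gave as many as the 2 genes of the real one, the highest other being 704, and in neck-like cells 2 of 35 gave as many as 3, the highest other being 606, so chance is not excluded for either. In both, the larger count came from the split of corpus replicates 1 and 2 and pylorus replicate 1 from the rest, several times the real count, which points to a structure of the plates. In the 4 similar plates, the real pairing gave 429 genes over all cells and 147 in neck-like cells. It gave 476 genes in parietal-like, 204 in pit-like, 39 in chief-like and 20 in endocrine-like cells. Each of the 2 other pairings gave 0 in these fits, but with 3 pairings the real one comes first by chance 1 time in 3. In proliferating-like cells of these plates the real pairing gave 20 genes and another pairing 2. In endocrine-like cells, 35 of 35 splits gave at least the 0 genes of the real one, the highest other being 3. For gene lists, 6 of 35 splits gave at least 8, the highest other being 9, so chance is not excluded. The pit-like, chief-like and proliferating-like cells and the comparison between classes have 10 splits each, too few for a share under 0.05, with 0 genes in the real split and 0 in the highest other, so that 10 of 10 gave as many.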
